A study of Mus musculus with 6 samples.

How the data were processed

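The data were bulk RNA sequencing libraries of aortic smooth muscle cells from mice 12 weeks old. Per the labels, 3 samples were wild type and 3 carried floxed miR-21 alleles, and both genotypes carried mTmG, a fluorescent Cre reporter, and Myh11ERT2, an inducible driver placed under the smooth muscle myosin gene. The floxed samples are called miR-21 knockout here, after the series' own wording. Whether an inducer was given, how the cells were isolated or cultured, and whether each sample came from its own animal are not given in the sources used here. The p-values below therefore measure the spread between these samples, part of which may be technical.

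Per the labels' protocols, RNA was extracted with Trizol from frozen cells and libraries were built from total RNA with the Illumina TruSeq RNA kit. Whether the libraries or the counting kept strand is not given in the sources used here and was not tested, so counts of overlapping or antisense genes are uncertain. The submitters' processing notes name STAR 2.6, DESeq2 and the mouse build mm10. The counting tool is not given in the sources used here. The deposited table holds expected counts per gene without normalisation, as read from the values, since 65.4% of its values lay within 0.01 of a whole number and the 6 column totals differed. It has 20199 genes, of which 14195 are marked protein-coding. Genes of the mitochondrial genome were not analysed here, so no mitochondrial share is given. In the deposited file 18 gene symbols read as dates, and these genes are not named. The deposited stop coordinate lay 1 base past the gene end of the mm10 gene table, so 1 was subtracted from it, and positions below are 1-based on mm10.

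The expected counts were rounded to whole numbers. Library totals after rounding ran from 17123748 to 28610649. Genes were kept with the default of filterByExpr, which left 15185 genes, and libraries were scaled with TMM factors. The main test was edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest with robust=TRUE, package default for the deviances, R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Dispersions were also estimated with robust=TRUE, a setting not fixed beforehand. Standard errors of log2 fold changes were taken as the size of the fold change divided by the square root of its F value. CPM values are TMM-scaled and given as mean ± SD of the 3 libraries of a group. Log2 CPM for correlations, principal components and list scores used a prior count of 2. A list score is the mean over a list's members of log2 CPM after each gene was centred on its mean over the 6 libraries.

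The following choices were made before the data were examined: the test, the gene lists, the rule for naming genes and most of the alternative settings. The 26 gene lists, written from textbook knowledge, covered contractile smooth muscle, modulated smooth muscle, fibrillar matrix and crosslinking, reported miR-21 targets, cell cycle, inflammatory cytokines and NF-kB response, interferon response, TGF-beta and BMP response, osteochondrogenic genes, cholesterol synthesis and uptake, lipid handling and lysosome, oxidative phosphorylation, glycolysis and hypoxia, unfolded protein and heat shock, immediate early and dissociation stress, the circadian clock, sex-linked genes, and markers of macrophages, lymphocytes and granulocytes, endothelium, adventitial fibroblasts, adipocytes, nerve and Schwann cells, striated muscle, mesothelium and epithelium, and erythroid cells. None was chosen on these samples. Each list was tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, adjusted over the 26 lists. Members were also adjusted over the list alone.

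The naming rule took genes with ordinary symbols, a mean CPM of at least 1 and no overlap between the groups. Since no gene passed the threshold, its last step applied, which takes the 6 genes with the smallest unadjusted p in each direction; the fold change condition could not be kept at that step. From each list the rule allowed the 4 members with the smallest p, plus Pdcd4, Spry1, Reck, Timp3 and Btg2 among the reported targets and Myh11, Acta2, Tagln and Cnn1 among the contractile genes. Named outside the rule, after their values were seen, were Idi1, Cyp51, Hmgcs1, Pmvk, Manf, Hsp90aa1 and Hspa1b, which passed when adjusted over their list alone, and 2610507I01Rik, Gm9493, Gbp2b, Trim12a and Mrpl55. A few genes that the rule or a list adjustment would name are not reported here, though they stay in the counts and tests.

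Seed matches of miR-21-5p were searched in the longest annotated 3′ UTR of each tested protein-coding gene. Transcripts came from GENCODE vM1, which is built on NCBIM37 and not on mm10, so they gave sequence only and no coordinates. Of 12416 such genes, 11009 (88.7%) matched by symbol and had a 3′ UTR of at least 20 bases. The sites were ATAAGCT (7mer-m8) and TAAGCTA (7mer-A1). The coefficient of site presence in a linear model of log2 fold change, with UTR length and GC content as further terms, was ranked among the same coefficients of 418 other 7-mers with the base composition of ATAAGCT.

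The alternatives were DESeq2 1.42.0, limma voom, DESeq2's size factors, library totals only, no expression filter, a stricter filter (CPM of at least 1 in 3 libraries), the replicate number as a block, stricter thresholds and leaving out each library in turn. Added after the data were seen were bias-adjusted deviances in edgeR, voom with sample weights, DESeq2 without wild-type replicate 1, camera with an estimated correlation without that library, and a chromosome test of the 50 genes with the smallest p and of DESeq2's calls, because the test of called genes by chromosome, fixed earlier, needed genes past edgeR's threshold.

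The tests were checked on simulated counts of 14923 genes with the means and totals of these libraries. With 100 genes changed by a log2 fold of 1 and 100 by a log2 fold of 2, edgeR recovered 71% and 97% of them, DESeq2 75% and 96%, and voom 67% and 94%. False calls made up 11.1% of edgeR's 189 calls, 18.6% of DESeq2's 210 and 9.04% of voom's 177. Genes were drawn independently and no library was made to stand apart, so these rates need not hold for the real libraries.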

Results

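The study profiled messenger RNA of aortic smooth muscle cells, the contractile cells of the vessel wall, from mice 12 weeks old. The mice were wild type or carried floxed miR-21 alleles (called knockout here), with 3 libraries per genotype. The question is how the transcriptome of these cells differs between the genotypes. Deletion of the microRNA miR-21 in the samples called knockout was not checked here. The cells carried a strong smooth muscle signature in both genotypes. Acta2, the smooth muscle actin gene, took between 1.94% and 2.49% of all counts in every library. Library totals were 17123748, 20177471 and 28610649 counts in wild-type replicates 1, 2 and 3 and 17216701, 22266480 and 27568002 in knockout replicates 1, 2 and 3. Pairwise Pearson correlations of log2 CPM across genes, which are not independent replicates, ran from 0.961 to 0.986. No pair of libraries was alike within counting noise, with a chi-square per gene between 14.2 and 102.

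Wild-type replicate 1 stood apart from the other libraries. The first principal component held 40.6% of the variance and placed it at −58.1, against 1.53 to 27.3 for the other 5 libraries. Its 10 largest genes took 12.4% of its counts, against 9.80% to 10.5% elsewhere. Lars2 and CT010467.1, a pair of features that commonly collect ribosomal reads, together took 3.31% of its counts, against 1.73% to 2.31% in the other libraries. The second component held 20.05% of the variance, with the wild-type libraries at −5.93, −22.5 and −15.3 and the knockout libraries at −1.49, 36.6 and 8.68.

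**Figure D1:**
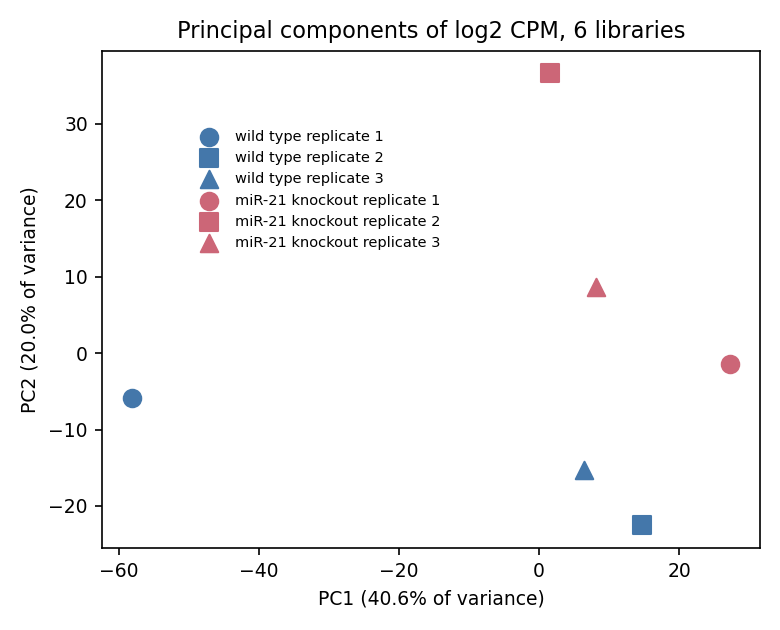
Principal components 1 and 2 of log2 CPM over the 15185 genes tested, 1 point per library, with colour for genotype and shape for replicate number. Wild-type replicate 1 lies at −58.1 on the first component, and the other 5 libraries lie between 1.53 and 27.3.

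The targeted locus lies at the 3′ end of Vmp1, a gene of autophagosome formation. On mm10, Mir21a, the gene of the miR-21 hairpin, occupies chromosome 11 from 86584067 to 86584158, and Vmp1 runs on the minus strand from 86583865 to 86683836. Vmp1 was at 47.9 ± 4.40 CPM in wild type and 54.5 ± 4.33 CPM in knockout. Its counts were 886, 865 and 1345 in wild-type replicates 1 to 3 and 917, 1324 and 1453 in knockout replicates 1 to 3. The difference did not pass (log2 fold change 0.19 ± 0.12 SE, edgeR adjusted p = 0.778; 2-sided exact permutation test of log2 CPM, p = 0.3, where 3 against 3 cannot go below 0.1). Mir21a itself was not analysed here, and a library of long RNA does not measure the mature microRNA, so the genotype labels were not checked by the deleted gene. Reads of the miR-21 primary transcript and of Vmp1 were not told apart here where the transcripts overlap.

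Among single genes, those with the smallest p-values included enzymes of sterol synthesis, all lower in the knockout. Lrrc32, which encodes the surface receptor that holds latent TGF-beta, was at 174 ± 11.4 CPM in wild type and 92.5 ± 8.35 CPM in knockout (log2 fold change −0.91 ± 0.12 SE). Scpep1, a serine carboxypeptidase gene on chromosome 11 from 88924020 to 88955465, was at 225 ± 7.88 and 132 ± 3.08 CPM (−0.77 ± 0.11). Sntg2, which encodes a syntrophin of the dystrophin complex, was at 23.7 ± 0.575 CPM in wild type and 40.2 ± 2.39 CPM in knockout (0.76 ± 0.11). Other genes that the naming rule took as lower in knockout included Sqle (−0.90), Fdps (−0.79) and Erdr1 (−1.74). Those taken as higher were Lrrc14b (3.12), Etv5 (0.94), Art3 (0.92), Mamdc2 (0.82) and Coq8a (0.62). Etv5 is a transcription factor of the ETS family, and Coq8a acts in coenzyme Q synthesis. Lrrc14b was near its detection limit in wild type, with 2, 2 and 10 counts against 41, 42 and 37 in knockout. Erdr1 spread widely in wild type (147 ± 74.3 CPM, against 44.1 ± 8.65 CPM in knockout), and it lies in the region shared by the sex chromosomes, which makes its count uncertain.

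None of these differences passed edgeR's test over all genes, where 0 of 15185 genes had an adjusted p under 0.05. The smallest adjusted p was 0.122, for the noncoding transcript 2610507I01Rik, and the genes named above had adjusted p-values from 0.219 for Lrrc32 to 0.489 for Coq8a. At an unadjusted p under 0.05 edgeR listed 955 genes, 433 higher and 522 lower in knockout, where 759 would be listed by chance. With library totals in place of TMM factors that split turned to 643 higher and 376 lower. With TMM factors, the listing shrank to 601, 638 and 630 genes without knockout replicates 1, 2 and 3, each under the 759 of chance. It grew to 1140, 1054 and 1244 without wild-type replicates 1, 2 and 3. The groups did not overlap for 2205 genes (14.5%), where chance gives 10%. DESeq2 called 69 genes, 17 risen and 52 fallen, among them all those named above, and limma voom called 0, with 990 at an unadjusted p under 0.05. DESeq2's adjusted p was 4.27e-09 for Scpep1, 4.02e-08 for Lrrc32 and 0.0140 for Coq8a. Of DESeq2's 69 genes, 61 were among the 69 with the smallest p in edgeR. Without wild-type replicate 1, edgeR called 9 genes. Among them Sntg2 and Gm9493 rose, and Lrrc32, Scpep1, Sqle, Srebf2, Erdr1 and 2610507I01Rik fell; all 9 were also among DESeq2's 69. Without wild-type replicate 2 it called 1 gene, Trim12a. Without that first wild-type library DESeq2 called 79 genes, 54 of them shared with its 69. In simulated data 18.6% of DESeq2's calls and 11.1% of edgeR's were false. Those data had no correlation between genes and no library standing apart, so the rates need not hold here.

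Genes of cholesterol synthesis and uptake were lower in the knockout almost throughout the list. Of 21 members tested, 20 had a lower fitted mean, with a median log2 fold change of −0.52. Sqle, the gene of squalene epoxidase, was at 43.4 ± 7.88 CPM in wild type and 23.3 ± 1.67 CPM in knockout, and Fdps, the gene of farnesyl diphosphate synthase, at 32.1 ± 5.09 and 18.6 ± 0.263 CPM. Srebf2, the transcription factor gene that drives this pathway, was at 195 ± 4.13 and 131 ± 2.52 CPM (log2 fold change −0.57). Idi1, which encodes isopentenyl diphosphate isomerase, was at 30.1 ± 10.1 and 14.9 ± 1.84 CPM (−1.01). Adjusted over the list alone, edgeR gave 9 fallen genes, among them Sqle, Fdps, Srebf2, Idi1, Cyp51, Hmgcs1 and Pmvk, and the groups of each did not overlap. Without wild-type replicate 3 the log2 fold change went from −0.77 to −0.43 for Cyp51 and from −0.59 to −0.35 for Hmgcs1. Over all genes tested, 0 members passed in edgeR and 6 in DESeq2, all fallen. The list ranked below the other genes in camera with the preset correlation (adjusted p = 1.19e-19), and had an adjusted p = 0.340 with an estimated correlation. The list score was 0.05, 0.19 and 0.53 in wild-type replicates 1 to 3 and −0.30, −0.25 and −0.21 in knockout replicates 1 to 3, so wild-type replicate 1 lay nearest to the knockout.

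**Figure D2:**
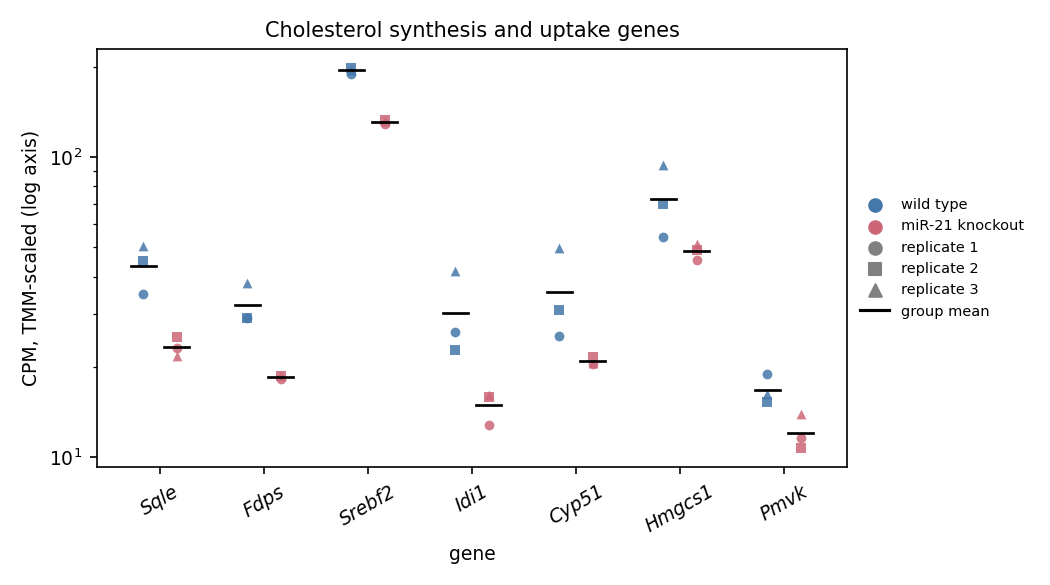
TMM-scaled CPM on a log axis of 7 cholesterol genes that fell when adjusted over the list alone, 1 point per library with the group mean as a bar. The knockout libraries lie below the wild-type libraries in each gene, for example 131 against 195 CPM in the group means of Srebf2.

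Among genes of lipid handling and the lysosome, 1 passed when adjusted over the list alone. Apoe, the gene of the lipid carrier apolipoprotein E, was at 130 ± 55.4 CPM in wild type and 52.7 ± 16.3 CPM in knockout (log2 fold change −1.30). It was the member of 21 that fell on that adjustment, and DESeq2 also called it. Apoe was at 194 CPM in wild-type replicate 1, against 96.1 and 100 CPM in wild-type replicates 2 and 3. Without wild-type replicate 1 its DESeq2 log2 fold change went from −1.29 to −0.89, and that call stayed. Abca1, which encodes a cholesterol exporter, was at 14.6 ± 4.68 and 28.1 ± 6.98 CPM (0.94) and did not pass (edgeR adjusted p = 0.0540 over the list). Over all genes 0 members passed in edgeR. The fitted mean was lower in knockout for 16 of the 21 (median −0.14), with a camera adjusted p of 0.0480, and adjusted p = 0.340 with an estimated correlation. Leaving out any 1 of the 6 libraries ended that call, with adjusted p-values from 0.0514 to 0.144.

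Chaperone genes were also lower in the knockout. In the unfolded protein and heat shock list, 21 of 23 members had a lower fitted mean, with a median log2 fold change of −0.38. Hspa8, the constitutive cytosolic chaperone, was at 956 ± 162 CPM in wild type and 510 ± 92.5 CPM in knockout (−0.91). Hsph1 (−1.02) and Hspb1 (−1.02), both chaperones of the heat shock response, lay apart between the groups too. Adjusted over the list alone, 7 genes fell in edgeR, namely Hspa8, Hsph1, Hspb1, Creld2, Manf, Hsp90aa1 and Hspa1b, of which Creld2 and Manf belong to the endoplasmic reticulum. Over all genes 0 passed in edgeR, and Hspa8, Hsph1 and Hspb1 fell in DESeq2. Without wild-type replicate 1, the DESeq2 calls of Hsph1 (log2 fold change −0.98, adjusted p = 0.299) and Hspb1 (−0.74, 0.570) ended and that of Hspa8 did not. Hspa1b has a near-identical copy, so its count is uncertain, and its wild-type spread was wide (651 ± 490 CPM, against 224 ± 54.1 CPM in knockout). Its log2 fold change was −1.54, and −0.72 without wild-type replicate 1. Camera gave an adjusted p of 2.91e-11 with the preset correlation, and adjusted p = 0.340 with an estimated correlation. The list score was 0.51, −0.17 and 0.33 in wild-type replicates 1 to 3 and −0.45, −0.06 and −0.16 in knockout replicates 1 to 3, so wild-type replicate 1 was the highest and wild-type replicate 2 lay among the knockout values.

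The immediate early and dissociation stress list, whose genes respond within minutes to handling, had 21 of 23 members with a lower fitted mean (median log2 fold change −0.24). Ier3 had the smallest p among them, at 257 ± 83.1 CPM in wild type and 165 ± 37.0 CPM in knockout (−0.64, and −0.34 without wild-type replicate 1). In edgeR 0 members passed over all genes or adjusted over the list alone, and 0 in DESeq2. Camera gave an adjusted p of 4.36e-04, and adjusted p = 0.577 with an estimated correlation. The score ranged within both genotypes, from 0.42 in wild-type replicate 1 to −0.12 in wild-type replicate 2 and from 0.28 in knockout replicate 2 to −0.68 in knockout replicate 1. The call ended without wild-type replicate 1 (adjusted p = 0.0920) and without knockout replicate 1 (0.749).

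**Figure D3:**
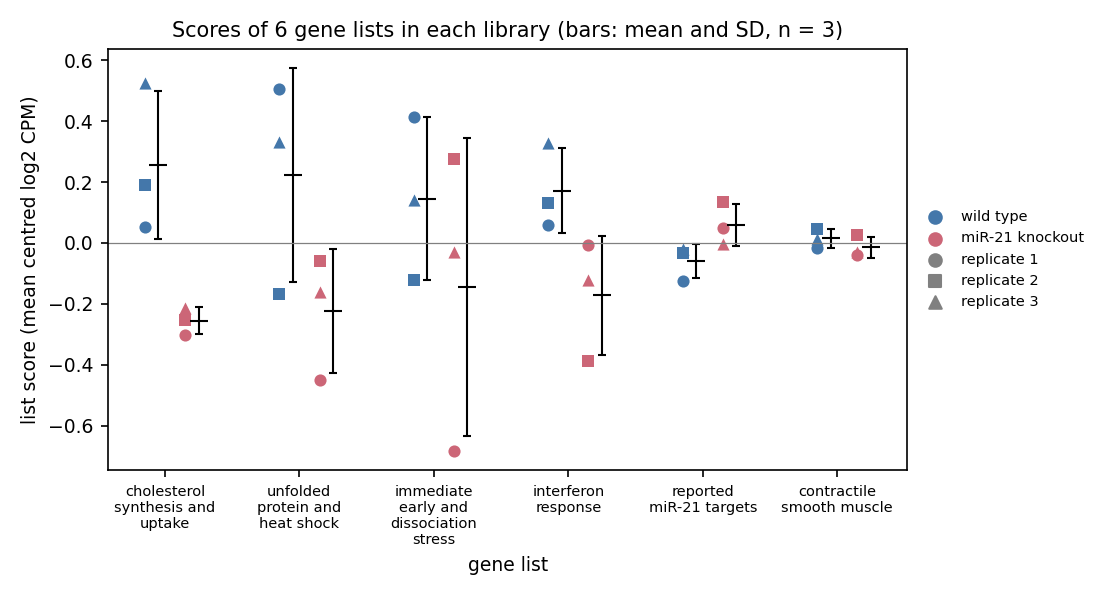
Scores of 6 gene lists (mean centred log2 CPM of the members), 1 point per library, with the mean and SD of the 3 libraries of each genotype. The cholesterol scores of the genotypes do not overlap (0.05 to 0.53 against −0.30 to −0.21), whereas those of the immediate early list do.

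A few inflammatory genes were lower in the knockout, and most interferon genes had a lower fitted mean without passing singly. Cxcl10, an interferon-induced chemokine gene, was at 3.904 ± 1.10 CPM in wild type and 1.60 ± 0.309 CPM in knockout (log2 fold change −1.27). The cytokine gene Il6 was at 9.55 ± 2.90 and 4.55 ± 0.933 CPM (−1.07), and the chemokine gene Cxcl1 at 95.7 ± 11.8 and 64.7 ± 11.1 CPM (−0.56). These were the 3 of 22 inflammatory members that fell when adjusted over the list alone, where Icam1 (−0.74), an adhesion molecule gene, missed the threshold (edgeR adjusted p = 0.0512 over the list). Icam1 was at −0.49 without wild-type replicate 1. Of the 22, 13 had a lower fitted mean (median −0.14). Over all genes 0 passed in edgeR, and Il6 fell in DESeq2 (adjusted p = 0.0437). That call ended without wild-type replicate 1 (log2 fold change −0.80, adjusted p = 0.197). In the interferon list 25 of 27 members had a lower fitted mean (median −0.26), among them the interferon-induced genes Isg15 (−0.83), Psmb8 (−1.22) and H2-K1 (−0.34). For H2-K1 the value without wild-type replicate 1 was −0.22. No interferon gene passed in edgeR over all genes or adjusted over the list alone (0 of 27), nor in DESeq2 (0). Camera gave adjusted p-values of 0.00108 for the inflammatory and 5.09e-05 for the interferon list, and for each adjusted p = 0.340 with an estimated correlation.

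Reported targets of miR-21 leaned upward in the knockout by a small amount. Of 41 tested, 29 had a higher fitted mean, with a median log2 fold change of 0.10. Spg20, the gene of spartin, was at 61.9 ± 11.2 CPM in wild type and 97.5 ± 8.52 CPM in knockout (0.65) and rose in DESeq2 (adjusted p = 0.0346), whereas edgeR gave an adjusted p of 0.507. Plekha1 (0.46), Reck (0.43), an inhibitor of matrix metalloproteinases, and Cdc25a (0.39), a cell cycle phosphatase, had positive values. Pdcd4, a translation inhibitor and a widely used miR-21 target, was at 11.2 ± 2.53 and 14.3 ± 2.13 CPM (0.35). Values were near 0 for Timp3 (0.12) and Btg2 (0.04), and Spry1 (−0.38) was lower. In edgeR 0 targets passed over all genes and 0 adjusted over the list alone. Camera gave an adjusted p of 0.0244 for the list, and adjusted p = 0.340 with an estimated correlation. The preset call ended without wild-type replicate 1 (0.0725) and without knockout replicate 2 (0.171). Without wild-type replicate 1, Timp3 was at −0.03 and Reck at 0.28. Btg2 was at −0.38 without knockout replicate 2, and Pdcd4 at 0.55 without wild-type replicate 2.

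The seed sequence was then examined across the transcriptome. A miR-21-5p 7mer site occurred in the 3′ UTR of 1323 of 11009 genes searched (12.0%). The median log2 fold change was 0.08 with a site and −0.01 without, and without wild-type replicate 1 the median with a site was 0.02. After UTR length and GC content were taken into account, site presence added 0.0078 to the log2 fold change, where 418 control 7-mers gave −0.033 to 0.034 with a median of 0.0061 (2-sided exact rank among the controls, p = 0.859). Genes with the 8mer ATAAGCTA had a coefficient of 0.025 (exact rank among the controls, p = 0.294). Among the 41 reported targets, 18 held an 8mer in the searched sequence, including Spg20, Reck, Pdcd4, Cdc25a, Plekha1, Timp3 and Spry1. Another 14 held a 7mer, including Btg2, and 9 held neither.

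Contractile genes, the markers of differentiated smooth muscle, differed little. Myh11 was at 8752 ± 1899 CPM in wild type and 9920.5 ± 983.6 CPM in knockout (log2 fold change 0.18 ± 0.18 SE), and Acta2 was at −0.10 ± 0.15 and Tagln at −0.18 ± 0.15. Cnn1, the calponin gene, had the smallest p among them (−0.32 ± 0.14) and did not pass. Of 30 tested, 11 had a higher and 19 a lower fitted mean (median −0.05), and 0 passed in edgeR over all genes or adjusted over the list alone. Camera gave an adjusted p of 0.377.

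Matrix genes were mixed, and elastin had the lowest fold change of the fibrillar matrix list. Eln was at 12577 ± 4099 CPM in wild type and 6569 ± 284 CPM in knockout (log2 fold change −0.94), and Mfap5, a gene of elastic microfibrils, at 242 ± 38.9 and 165 ± 7.57 CPM (−0.55). Both fell when adjusted over the fibrillar matrix and crosslinking list alone, where 12 of 32 members had a higher and 20 a lower fitted mean (median −0.09). Serpinh1, the collagen chaperone gene (−0.43), and P4ha1, a collagen hydroxylase gene (−0.65, and −0.37 without wild-type replicate 3), did not pass. In the modulated smooth muscle list, Mmp2, a gelatinase gene, fell when adjusted over the list alone (45.0 ± 3.86 and 28.2 ± 3.04 CPM, −0.67), as did Eln. Those 2 were the only such members of 27, and the list's median was −0.0019. In the TGF-beta and BMP list, Tgfb2, a TGF-beta ligand gene, fell when adjusted over the list alone (184 ± 28.4 and 113 ± 17.2 CPM, −0.71), the 1 of 31 to do so, and Ctgf was at −0.66 without passing. Over all genes 0 members of these lists passed in edgeR, while Eln, Mmp2 and Tgfb2 fell in DESeq2. Eln was at 17306 CPM in wild-type replicate 1, against 10048 and 10378 CPM in wild-type replicates 2 and 3. Without wild-type replicate 1 its DESeq2 log2 fold change went from −0.93 to −0.63, and that call stayed. Camera gave adjusted p-values of 0.00581 for the matrix list (adjusted p = 0.402 with an estimated correlation), 0.263 for the modulated list and 0.552 for the TGF-beta list. The matrix call ended without wild-type replicate 3 (0.0728) and without knockout replicate 3 (0.126). Adventitial fibroblast markers were also lowest in knockout replicate 3 (score −0.49, against −0.16 for the matrix list). They share Mfap5 and some collagen genes with the matrix list, so these scores are not independent.

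In the osteochondrogenic list, 10 of 16 members had a higher fitted mean (median log2 fold change 0.17). Ank, which encodes a pyrophosphate exporter, was at 75.2 ± 12.9 CPM in wild type and 110 ± 8.67 CPM in knockout (0.55). In edgeR 0 passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 0.0789, which became 0.0421 without wild-type replicate 1. That list had an adjusted p = 0.340 with an estimated correlation, and 0.425 with an estimated correlation without that library.

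Nuclear genes of oxidative phosphorylation were slightly lower in the knockout, with 27 of 29 below 0 and a median log2 fold change of −0.14. Ndufs4, a complex I gene, had the smallest p (−0.32, and −0.20 without wild-type replicate 1). In edgeR 0 members passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 0.00214, and adjusted p = 0.577 with an estimated correlation. The call ended without wild-type replicate 1 (0.234), whose score was 0.23, against −0.12 to 0.02 in the other libraries. Glycolysis and hypoxia genes went both ways, with 13 of 24 higher (median 0.01, camera adjusted p = 0.849). Pdk1, an inhibitor of pyruvate dehydrogenase, was at 0.47. Cell cycle genes had 16 of 27 lower (median −0.14, camera adjusted p = 0.434), and the cyclin-dependent kinase inhibitor gene Cdkn2b was at −0.67. In both of these lists 0 members passed in edgeR, over all genes or adjusted over the list alone.

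Few markers of immune and epithelial cells reached the level needed for a test, whereas markers of several other cell types were measured in both genotypes. Of 21 endothelial markers 13 were tested, of 22 adventitial fibroblast markers 21, and the globin gene Hba-a2 was at 234 ± 110 CPM in wild type and 257 ± 26.2 CPM in knockout. Of 26 macrophage markers, 8 were expressed enough to be tested, and Cd68 was at 1.76 ± 0.789 CPM in wild type and 0.925 ± 0.357 CPM in knockout. Of 23 lymphocyte and granulocyte markers, 1 was tested, the immunoglobulin gene Ighm, with 0, 25 and 2 counts in wild-type replicates 1 to 3 and 87, 20 and 35 in knockout replicates 1 to 3. Of 15 mesothelial and epithelial markers, 1 was tested, Krt18, at 16.4 ± 0.514 and 14.3 ± 4.36 CPM. Camera gave adjusted p-values of 0.356 for macrophage, 0.0789 for lymphocyte and granulocyte, 0.481 for mesothelial and epithelial, 0.513 for endothelial, 0.513 for adipocyte, 0.417 for nerve and Schwann, 0.350 for striated muscle, 0.263 for sex-linked and 0.717 for erythroid genes. Some of these passed when 1 library was left out. Macrophage markers passed without knockout replicate 2 (adjusted p = 0.0407), striated muscle markers without wild-type replicate 2 (0.0494), and Ighm without wild-type replicate 2 (0.00263) or knockout replicate 2 (0.0460). With an estimated correlation and all libraries, the adjusted p was 0.577 for macrophage, 0.577 for striated muscle and 0.340 for lymphocyte and granulocyte markers. Erythroid genes, mostly globins with near-identical copies, scored −0.96 in wild-type replicate 1, against −0.04 to 0.54 in the other libraries. Without that library they ranked lower in knockout (adjusted p = 0.00267), with adjusted p = 0.524 with an estimated correlation. Adventitial fibroblast markers ranked lower (13 of 21 with a lower fitted mean, median −0.15, camera adjusted p = 0.0322), with adjusted p = 0.577 with an estimated correlation. Their score was −0.49 in knockout replicate 3, against 0.01 to 0.17 in the other 5 libraries. The call ended without knockout replicate 3 (0.981), wild-type replicate 2 (0.0765) or wild-type replicate 3 (0.170). In these 10 lists 0 members passed in edgeR, over all genes or adjusted over the list alone.

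Across the 26 lists, camera with the preset correlation called 10, of which 9 were lower and 1, the reported miR-21 targets, higher in knockout. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05, and fry called 0 for a shift in 1 direction (smallest adjusted p = 0.167) and 0 for mixed changes (smallest adjusted p = 0.158). Without wild-type replicate 1 the preset test called 8 lists.

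**Figure D4:**
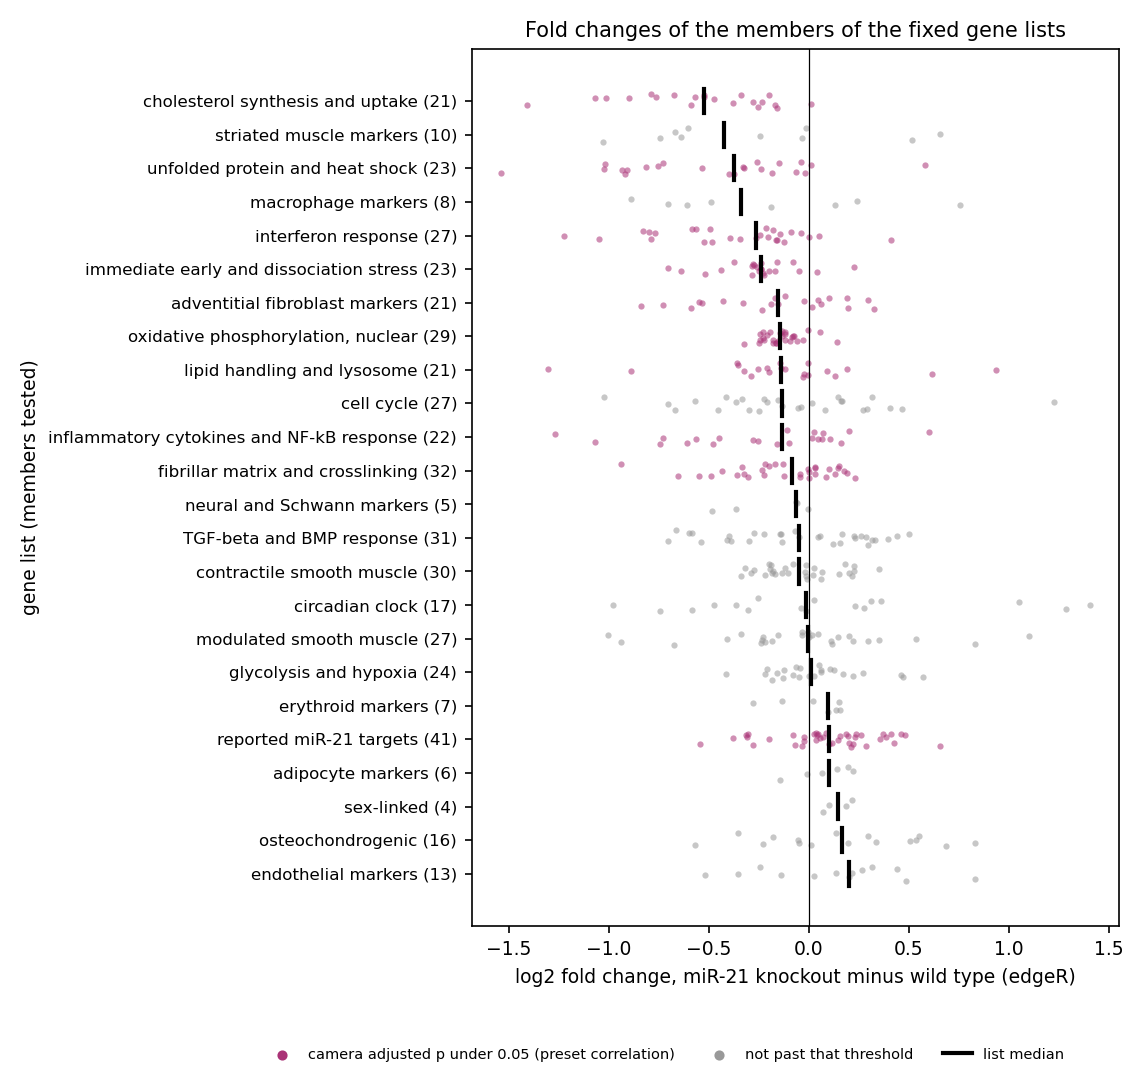
Log2 fold changes (knockout minus wild type) of the tested members of each list with more than 1 of them, 1 point per gene, with the list median as a black bar and colour for lists past the preset camera threshold. The cholesterol list has the lowest median, at −0.52.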

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

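With edgeR, 0 genes passed under DESeq2's size factors (964 genes at an unadjusted p under 0.05), library totals only (1019), no filter (1155), the stricter filter (890), stricter thresholds and, added after the data were seen, bias-adjusted deviances (986), and limma voom gave 0 (990). DESeq2 gave 69 genes (962 at an unadjusted p under 0.05), and leaving out 1 library in turn gave 0 to 9 in edgeR. Of other alternatives added then, voom with sample weights, which gave wild-type replicate 1 a weight of 0.252, called 10 genes, and DESeq2 without that library called 79. The cause of the difference between the tools was not tested. Camera called 10 lists with DESeq2's size factors and 7 to 10 with 1 library left out. It called 0 with an estimated correlation and 0 with an estimated correlation and wild-type replicate 1 left out (added later). Against the preset 0.01, the estimated correlation was 0.404 for the cholesterol and 0.465 for the heat shock list. It was 0.461 for oxidative phosphorylation and 0.781 for the immediate early list. The lipid handling list was at −0.020, below the preset value, and lost its call too. Lists with 1 tested member have no correlation to estimate, yet their unadjusted camera p rose too. It went from 0.0364 to 0.105 for Ighm and from 0.370 to 0.421 for Krt18. The change of setting therefore raised p-values apart from the correlation itself. How much each contributed to the lost calls was not tested. Same-numbered libraries did not deviate together, with correlations of −0.27, −0.18 and −0.08 for replicates 1, 2 and 3. Differently numbered libraries of opposite genotypes gave −0.11 to 0.21. Such deviations from means of 3 libraries cannot show whether same-numbered samples shared a day or litter, so pairing stays open. With the replicate number as a block, edgeR called 0 genes (572 at an unadjusted p under 0.05), camera called 11 lists, the same 10 and the lymphocyte and granulocyte list (Ighm alone, adjusted p = 0.0230), and the seed coefficient was 0.0092. The cholesterol, heat shock, interferon and inflammatory lists were past camera's threshold in all 8 alternatives that kept the preset correlation. Of the fold changes of the 70 named genes under all alternatives, 1040 stayed on the same side of 0 and of the threshold, 69 newly passed it and 11 turned sign. Btg2 was at −0.043 with voom and −0.039 with the replicate block, and at −0.38 to 0.28 with 1 library left out. Timp3 was at −0.024 in DESeq2 without wild-type replicate 1 and −0.026 to 0.26 with 1 library left out. Krt18 was at −0.43 to 0.015 with 1 library left out. Hba-a2 was at −0.10 with voom weights, −0.21 in DESeq2 without wild-type replicate 1 and −0.21 to 0.41 with 1 library left out. List directions turned with an estimated correlation and wild-type replicate 1 left out for glycolysis (adjusted p = 0.979), the circadian clock (0.813) and erythroid genes (0.524). With 1 library left out they turned for glycolysis (adjusted p from 0.749 to 0.981), the clock (0.274 to 0.946), erythroid genes (0.00267 to 0.993), cell cycle (0.1501 to 0.810), macrophage (0.0407 to 0.833), mesothelial (0.126 to 0.963) and modulated smooth muscle genes (0.0545 to 0.841); the cause was not tested. The Vmp1 difference stayed positive with library totals only (0.23), and its edgeR log2 fold change was 0.12 without knockout replicate 2. The seed coefficient stayed between 0.0036 and 0.025 in its alternatives without passing. The effect of depth was not tested.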

Other observations

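The tests of chromosome 11 below were chosen only after the result was seen. Genes of the circadian clock were scattered in both directions. Dbp, an output gene of the clock, was at 4.39 ± 1.497 CPM in wild type and 9.06 ± 2.72 CPM in knockout (log2 fold change 1.05), and Nr1d2, a repressor of the clock loop, at 22.7 ± 20.8 and 60.2 ± 9.94 CPM (1.40). Cry1 was at 28.0 ± 12.4 and 14.3 ± 2.16 CPM (−0.98) and Per2 at 42.8 ± 14.3 and 25.6 ± 3.54 CPM (−0.74), both repressors of the same loop. Single libraries moved these values, with Nr1d2 at 2.46 without wild-type replicate 2 and Cry1 at −0.58 and Per2 at −0.44 without wild-type replicate 3. In edgeR 0 of 17 members passed over all genes or adjusted over the list alone, where Dbp, Cry1 and Per2 each had an adjusted p of 0.0543 over the list. The list passed no test of a shift in 1 direction (camera adjusted p = 0.763, median −0.01, mean 0.07), and the mixed test of fry gave 0.0417 before adjustment and an adjusted p of 0.160.

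A search made after the values were seen found 3 genes present at 1 CPM or more in at least 2 libraries and under 0.06 CPM in at least 2 others. The noncoding 2610507I01Rik, on chromosome 11 from 59199836 to 59202385, had 25, 53 and 109 counts in wild-type replicates 1 to 3 and 0, 1 and 0 in knockout replicates 1 to 3, a ratio of 190 over the summed counts scaled by library totals (95% exact interval 33.7 to 7553, counting error only). Trim12a had 0, 211 and 0 counts in wild type and 226, 234 and 201 in knockout. Gbp2b had 78, 0 and 256 counts in wild type and 114, 0 and 0 in knockout, so these last genes varied within a genotype.

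The first pattern is the lower level of cholesterol genes in the knockout, a list score difference of −0.512 (95% interval −0.908 to −0.116). The tables argue against wild-type replicate 1 as the whole cause, since its score was the wild-type score nearest to the knockout. Leaving it out could therefore only widen the difference, to −0.613 (95% interval −1.03 to −0.20). Wild-type replicate 3, which had the highest score (0.53), was not weighed in this way. A trend with transcript GC content and length, which explained 9.69% of the variance of log2 fold changes, is argued against as the whole cause. After its removal the median of the 19 members with a transcript was −0.368 (−0.836 to −0.218), against −0.472 before. That interval is over genes, which are not independent replicates, so it does not measure the spread between libraries. Handling stress stays open, because with the heat shock score as a covariate the group coefficient was −0.497 with an interval of −1.22 to 0.227. An effect of the genotype itself stays open as well, untested apart from other differences between the samples.

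The second pattern is the lower mean level of heat shock and unfolded protein genes, a score difference of −0.446. Its 95% interval over the 6 libraries, −1.10 to 0.203, included 0, so the difference itself is uncertain. A trend with GC content and length is argued against as the whole cause, with a median of −0.340 (−0.787 to −0.106) after its removal, against −0.375 before. This interval too is over genes and does not measure the spread between libraries. Wild-type replicate 1 stays open as a cause, since the difference without it was −0.304 with an interval of −1.07 to 0.46. Handling stress stays open as well, since with the immediate early score as a covariate the coefficient was −0.270 (−0.784 to 0.245). A response to the genotype is possible and untested apart from these.

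The third pattern is that 7 of the 50 genes with the smallest p lie on chromosome 11, which holds the targeted locus. By its share of tested genes 3.80 would be expected there, and chromosome 5 also held 7 (3.38 expected). Scpep1 lies 2.34 Mb from Mir21a, and 2610507I01Rik and Mrpl55, which are neighbours, lie 27.4 Mb away. The rest of the 7 on chromosome 11 lie 28.0 to 63.1 Mb away. The gene at 28.0 Mb starts at 58608204, near 2610507I01Rik (59199836) and Mrpl55 (59202486), and all of these fell in DESeq2. The 7 genes therefore need not be separate hits. Chance placement stays open, since the adjusted Fisher p of chromosome 11 was 0.473. Among DESeq2's calls, chromosome 11 held 7 (5.24 expected, adjusted Fisher p = 0.650) and chromosome 5 held 10 (4.66 expected, 0.314). Within 10 Mb of Mir21a, 23 of 199 tested genes (11.6%) had an unadjusted p under 0.05, against 6.22% elsewhere, an odds ratio of 1.97 (1.21 to 3.07), and 4 of 124 windows of 20 Mb had a share as high. Alleles carried along with the targeted locus may contribute to single differences such as that of Scpep1, a hypothesis that these data leave open beside chance.

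The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, which are too few for a share under 0.05. For genes past edgeR's threshold, all 10 splits gave at least the real count of 0, and the highest other gave 1. For genes at an unadjusted p under 0.05, 2 splits gave at least the real count of 955, and the highest other gave 1183. For lists past camera's preset threshold, 1 split, the real one, gave 10 or more, and the highest other gave 9.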
